A study of Homo sapiens with 8 samples.

How the data were processed

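Chromatin of 2 human cell lines was measured by chromatin immunoprecipitation on promoter arrays (ChIP-on-chip). Kms12, a myeloma line, is the test line and Ly19, a lymphoma line, is the control line. In each hybridisation, DNA recovered with 10 ug of an antibody against the transcription factor IRF4 carried Cy5, and DNA recovered from the same line with 10 ug of normal goat serum carried Cy3. Per the labels' protocols, chromatin was cross-linked with formaldehyde and sonicated, and the recovered DNA was whole-genome amplified and labelled with random primers. The series' design text counts 2 biological replicates per line, called repeats here. P-values measure the spread between these 2 cultures or preparations of 1 line together with that of their image processing, whose background step differed between the repeats. Each repeat was spread over 2 array designs that carry different probes (237210 and 237201 probes, 0 shared), which makes 8 arrays. The slide labels of repeat 2 run the other way round from those of repeat 1, so arrays were matched by the design number in the file headers. No array was dye-swapped.

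The files are outputs of Agilent Feature Extraction. The submitters' processing notes name version 9.1.3.1, while the file headers give 9.5.1.1. Per the file headers, the authors' software turned each spot into background-adjusted, dye-normalised intensities for both channels and deposited the log10 ratio of Cy5 to Cy3. Per the file headers, the arrays of repeat 1 had a fitted background surface subtracted, whereas those of repeat 2 had a multiplicative detrending and no background removal. The deposited intensity of the negative controls after that step lay near 0 in repeat 1 and between 61.2 and 101 in repeat 2. The standard deviation of the log2 ratios was 0.54 to 0.65 in repeat 1 and 0.24 to 0.33 in repeat 2. Raw intensities per the file headers gave a median probe 2.06 to 4.56 times the negative controls in Cy5 and 1.69 to 2.22 times in Cy3. The number of arrays and this low signal over background limit the precision.

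The deposited log10 ratios were turned to log2 and centred on the median probe of each array. Probes marked by the authors' software as saturated, non-uniform or population outliers in either channel of any array were left out. Log ratios were averaged in windows of probes with midpoints within 500 bp of each probe, with at least 3 probes per window. The median probe spacing was 177 and 178 bp, and 424963 windows were tested. Each array design was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the data.table package, 1.17.8) with 1 mean per line. Two-sided p-values of both designs were adjusted together by the Benjamini-Hochberg method. A window was called at an adjusted p below 0.05 and at least a 1.5-fold difference, and called windows of 1 direction within 1000 bp were joined to 1 region. Kms12 minus Ly19 was the main contrast, because a probe's dye effect cancels in it as far as it is the same in every array. The dependence of the ratio on probe GC content differed between arrays, as given below. Each line was also tested against 0, where IRF4 and Cy5 cannot be separated. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

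Positions and gene names are those in the files, and the genome build is not given in the sources used here. Of 17280 array genes, 16957 matched a current symbol in a RefSeq gene table, and for 4287 of them the current symbol differs; array symbols are printed, with a current symbol at first mention where it helps. The files class each probe as promoter, inside a gene, divergent promoter, downstream or unknown, and for most probes give a distance from the transcription start. They do not separate exon, intron or untranslated region.

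Gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The 13 lists hold plasma cell, germinal centre and B cell, interferon response, antigen presentation, unfolded protein response and secretion, MYC and cell cycle, sterol and fatty acid synthesis, glycolysis, NF-kappaB and BCL2 family, T and NK cell, myeloid cell, liver, muscle and nerve, and housekeeping genes. The liver, muscle and nerve list and the T, NK and myeloid cell lists stand for cell types that neither line represents. Lists were compared with the other genes by 2-sided Fisher exact tests on genes with a called region, and by camera (limma, preset correlation 0.01, with the estimated correlation beside it) on the mean log2 ratio of each gene's probes within 1000 bp of its start (16879 genes). The rule names IRF4, MYC and PRDM1 always. It adds the 15 genes with the largest called difference toward Kms12 and the 5 toward Ly19, given that the 2 arrays of one line lie above the 2 of the other. It also adds up to 4 members of each list, the 8 genes with the largest enriched window per line, and the 5 largest enriched in both. Some genes picked by this rule or by a list test are not reported here.

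Because the deposited log ratios gave 0 called windows, the parts of the rule that need a call were applied to the calls after quantile normalisation, an alternative fixed in advance. That step was chosen after the calls under the alternatives had been seen. The other alternatives fixed in advance were narrower and wider windows (250 and 1000 bp), single probes, a 2-fold and no fold threshold, an adjusted p below 0.01, no centring, loess within arrays, scaling to a common spread, no probes or also dim probes left out, a trended and robust spread, the repeat number as a block, a shorter joining distance (500 bp), spread from 1 line only, calls within 1000 bp of the start, all probes of a gene, and each repeat of a line left out in turn. A further 7 settings were added after the data had been seen. They are a common background step (the median negative control subtracted, with a floor of 20), removal of a lowess trend on probe GC content (span 0.3), and combinations of these, of scaling and of quantile normalisation with the block or with each other.

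Repeat numbers were taken to pair the arrays of the 2 lines as a processing batch, since the background step in the file headers goes with the repeat number. Deviations of same-numbered windows from their line's mean correlated at 0.356 in the check of this pairing. Blocked values stand beside a result where they change a call or move a count by over 1.5 times.

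The planned motif search in the reference sequence was not run because no genome of the files' build was used here. Probe sequences in the files were searched instead, for GAAA pairs and GGAA with GAAA at 0 to 6 bases of spacing. Regions were compared with 20 random runs of uncalled windows each.

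The fit was tested on simulated data before use. For the spread of each array, the real ratios of each array were moved along the genome by a random offset of its own. This removed the agreement between arrays and left real peaks in the noise. For equal spread, probe values were independent draws from a normal distribution. The recovery rates, with and without the block, therefore do not give the power in these data. With the spread of each array, 0% of 68 regions simulated at 2-fold, 56.1% of 66 at 4-fold and 89.4% of 66 at 8-fold were recovered, with 0 regions called elsewhere. With equal spread in all arrays, 91.2%, 87.9% and 98.5% were recovered and 14 regions were called elsewhere. With the block and the spread of each array, recovery was 1.5%, 80.3% and 93.9%, with 0 regions elsewhere. With the block and equal spread it was 86.8%, 97% and 90.9%, and 46 regions were called elsewhere. In 50 simulated runs on 16000 genes, camera called a list of 30 genes shifted by 0.5 in 50 and an unshifted list in 3. The simulated genes were independent and the shift exceeded those found below, so these runs do not cover lists of correlated genes or smaller shifts. Quantile normalisation was not part of any simulation.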

Results

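The data comprise log2 ratios of IRF4 antibody to normal serum DNA at 17280 promoters on 8 arrays, with 2 repeats of the myeloma line Kms12 and 2 of the lymphoma line Ly19. IRF4 belongs to the interferon regulatory factor family and is needed for plasma cell differentiation. All ratios are log2, centred on the median probe, with SD over n = 2 repeats per line, and positions follow the array files, whose genome build is not given. Across probes, which are not independent replicates, the Kms12 repeats correlated at Pearson's r = 0.181 and 0.202 on the 2 array designs (Spearman's coefficient 0.156 and 0.184). The Ly19 repeats correlated at r = 0.398 and 0.454 (Spearman 0.374 and 0.43). The 2 lines of repeat 1 correlated at 0.443 and 0.399, so that Kms12 repeat 1 was closer to Ly19 repeat 1 than to the other Kms12 repeat. By Pearson's r the Kms12 repeats were no closer to each other than to any Ly19 array (0.181 to 0.443 and 0.231 to 0.399). Spearman's coefficient was lower for Kms12 repeat 2 with Ly19 repeat 2 on the first design (0.072) and with Ly19 repeat 1 on the second (0.175). The agreement of the Kms12 repeats depended on the processing. Over window means they correlated at 0.376 on the deposited ratios, 0.540 with a common background step and 0.553 with loess within arrays. The Ly19 repeats were at 0.603, 0.563 and 0.595, and the 2 lines of repeat 1 at 0.564, 0.591 and 0.558.

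The main comparison asked which promoters carried more IRF4 over serum in the myeloma line than in the lymphoma line. PRDM1, which encodes the plasma cell regulator BLIMP1, showed a 2.54-fold difference in a window on chromosome 6 from 106642305 to 106643164, inside the gene 1796 bp downstream of its start. There the ratio was 1.14 ± 0.07 in Kms12 and -0.21 ± 0.13 in Ly19. ELL2, an elongation factor that acts in immunoglobulin secretion, differed by 1.12 inside the gene, 2149 bp downstream of its start (chromosome 5, 95320922 to 95321832). TNFAIP3, which encodes the NF-kappaB inhibitor A20, differed by 1.34 inside the gene, 2381 bp downstream (chromosome 6, 138232384 to 138232794; 1.32 ± 0.28 against -0.02 ± 0.09). These windows were called higher in Kms12 after quantile normalisation (limma, adjusted p = 0.0228, 0.0296 and 0.016), but on the deposited ratios their adjusted p was 1.

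From the deposited ratios limma called 0 of 424963 windows in either direction, with 6601 windows at an unadjusted p below 0.05 toward Kms12 and 6158 toward Ly19. Together these 12759 windows lay under the share of 0.05 expected without any difference between the lines, so they are no excess. Quantile normalisation gave 66 regions (231 windows, 59 genes) higher in Kms12 and 131 regions (411 windows, 111 genes) higher in Ly19. The Ly19 side had been planned also as a check on the rate of false calls, and it called more regions than the Kms12 side. A trended and robust spread gave 67 and 113 regions, although only 7 and 82 of its windows were among those called after quantile normalisation. With the repeat number as a block the deposited ratios again gave 0 and 0 regions, and the quantile-normalised ratios 480 and 1040. Removal of the GC trend before quantile normalisation left 0 and 0 regions (smallest adjusted p = 0.127). Without Kms12 repeat 2 the deposited ratios gave 2327 regions toward Kms12 and 203 toward Ly19, and without Ly19 repeat 2 they gave 4 and 33; without either repeat 1 there were 0.

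**Figure D1:**
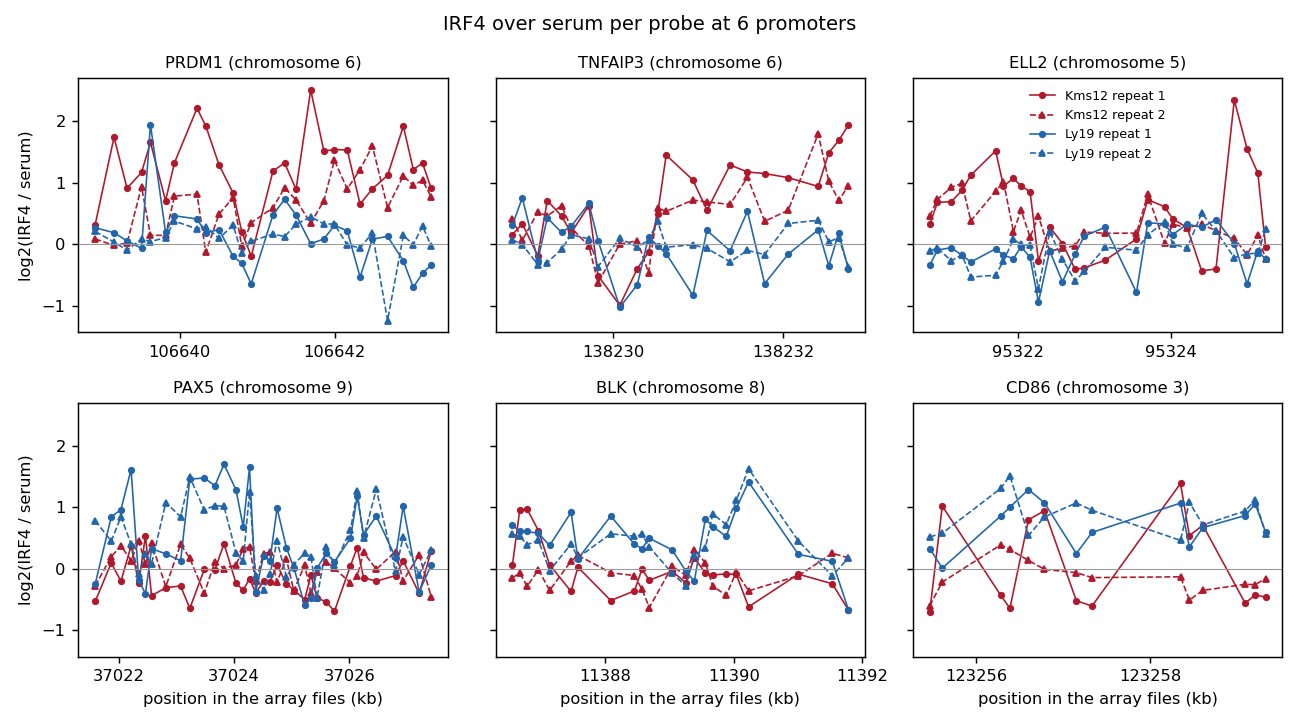
Log2 ratio of IRF4 to serum (vertical axis) per probe against position in kb (horizontal axis) at 6 promoters, with 1 line per array (red, Kms12; blue, Ly19; circles and solid lines, repeat 1; triangles and dashed lines, repeat 2). On average over the window reported for each gene, both Kms12 arrays lie above both Ly19 arrays at PRDM1, TNFAIP3 and ELL2, and below them at PAX5, BLK and CD86; single probes of the called regions depart from this.

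Other genes were among the 15 with the largest difference after quantile normalisation. ARHGAP24, a GTPase activator, differed by 1.53 (adjusted p = 0.00199) and SSTR2, a somatostatin receptor, by 1.51 (adjusted p = 0.00702). SMOC1 differed by 1.45, TP73L (now TP63, a p53 family factor) by 1.41, HSDL2 by 1.37 and LRIG3 by 1.15. In these genes the Kms12 minus Ly19 difference was between 0.84 and 2.03 in each repeat, and larger in repeat 1.

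In other genes of the 15, too, repeat 1 gave the larger difference. C21orf25 (now C2CD2) had the largest mean difference, 1.93, made of 3.08 in repeat 1 and 0.78 in repeat 2. CASP4, an inflammatory caspase, differed by 1.64 at its start (2.50 and 0.77), RAB6IP1 by 1.59 (2.65 and 0.54), GIMAP2 by 1.58 (2.19 and 0.98) and COMMD3 by 1.52 (2.07 and 0.96). DENND2C differed by 1.67 (2.83 and 0.52), and there the serum signal itself was lower in Kms12, by -2.14 in repeat 1 and -1.09 in repeat 2. The plot of named genes shows this spread. None of these genes passed on the deposited ratios (adjusted p = 1 for each).

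**Figure D2:**
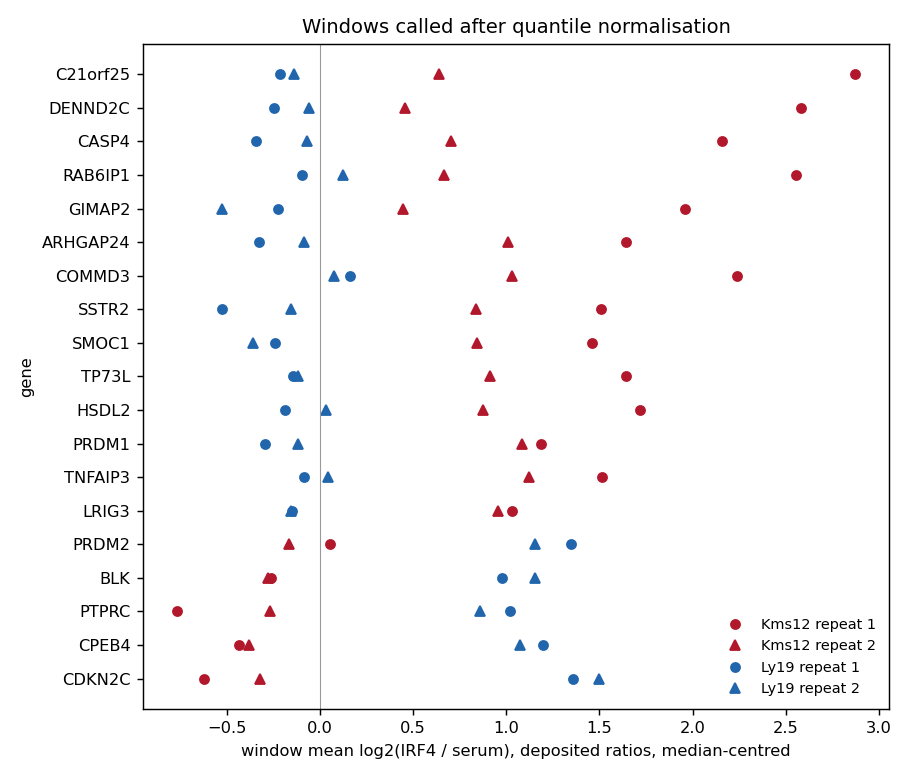
Window mean log2 ratio of IRF4 to serum (horizontal axis) in each array for the genes (vertical axis) with the largest called differences after quantile normalisation, drawn from the deposited, median-centred ratios (red, Kms12; blue, Ly19; circles, repeat 1; triangles, repeat 2). For the genes shown that were called toward Kms12 both red points lie above both blue points, and for the 5 called toward Ly19 both blue points lie above.

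IRF4 and MYC were examined whether called or not. For each, the window with the largest difference between the lines is given, so its unadjusted p was picked on the quantity it tests. At the IRF4 gene itself, 2290 bp inside, the ratio was 0.67 ± 0.31 in Kms12 and -0.25 ± 0.11 in Ly19, a difference of 0.92 (unadjusted p = 0.00326; adjusted p = 1, and 0.079 after quantile normalisation). At MYC, which drives growth and proliferation, at -942 bp from the start, the ratio was 0.76 ± 0.17 and -0.06 ± 0.08, a difference of 0.82 (unadjusted p = 0.00377; adjusted p = 1, and 0.151 after quantile normalisation). Neither passed the threshold.

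Plasma cell genes lay on average 0.18 higher in Kms12 than in Ly19 (0.26 ± 0.13 against 0.08 ± 0.05), by 0.24 in repeat 1 and 0.12 in repeat 2. Of 25 measured members, 14 had both Kms12 values above both Ly19 values and 0 the reverse. Over all 16879 genes the shares were 17.9% and 8.03%. Interferon response genes lay 0.27 higher (0.32 ± 0.15 against 0.05 ± 0.03; 0.35 and 0.19 in the repeats), with both Kms12 values above both Ly19 values in 25 of 41 members. Germinal centre and B cell genes differed the other way, by -0.19 (0.07 ± 0.08 against 0.26 ± 0.05; -0.17 and -0.20), with both Ly19 values above both Kms12 values in 18 of 32 members. The mean over all genes was 0.04. Camera with its preset correlation called these 3 of the 13 lists (adjusted p = 0.00577, 3.09e-09 and 3.6e-10). With an estimated correlation none was called (adjusted p = 0.402, 0.402 and 0.304). The plasma cell list was also not called without Kms12 repeat 1 (adjusted p = 0.0684).

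Few single members of these lists passed a test. On the deposited ratios 0 genes of any list passed when adjusted over the list alone, and 0 of 16879 over all genes (limma). Of all genes 289 had an unadjusted p below 0.05, under the share of 0.05 expected without any difference. With the repeat number as a block, the members that passed adjusted over the list alone included 3 plasma cell genes (CD28, PRDM1 and TNFRSF17), 8 interferon response genes (DDX58, G1P3, IFIH1, IFIT1, IFIT3, MX2, OASL and USP18), CDKN2C and CYBB, against 0 genes over all genes. After quantile normalisation 18 genes passed over all genes, none of them in the plasma cell, B cell or interferon lists, while adjusted over the list alone 4, 5 and 7 members did. Of the 4 plasma cell genes 3 were higher in Kms12 and IGJ (now JCHAIN) was higher in Ly19, the B cell genes were all higher in Ly19, and the interferon response genes all higher in Kms12. PRDM1 and ELL2 made 2 of 26 plasma cell genes with a region called toward Kms12 (7.69%, against 0.33% of other genes; Fisher exact test, adjusted p = 0.0459 over 13 lists). IFIH1, an RNA sensor, CDKN1B, a cell cycle inhibitor, and TNFAIP3 were the only members with such a region in the interferon, cell cycle and NF-kappaB lists (adjusted p = 0.426 each). This test had 0 called genes in every list on the deposited ratios.

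**Figure D3:**
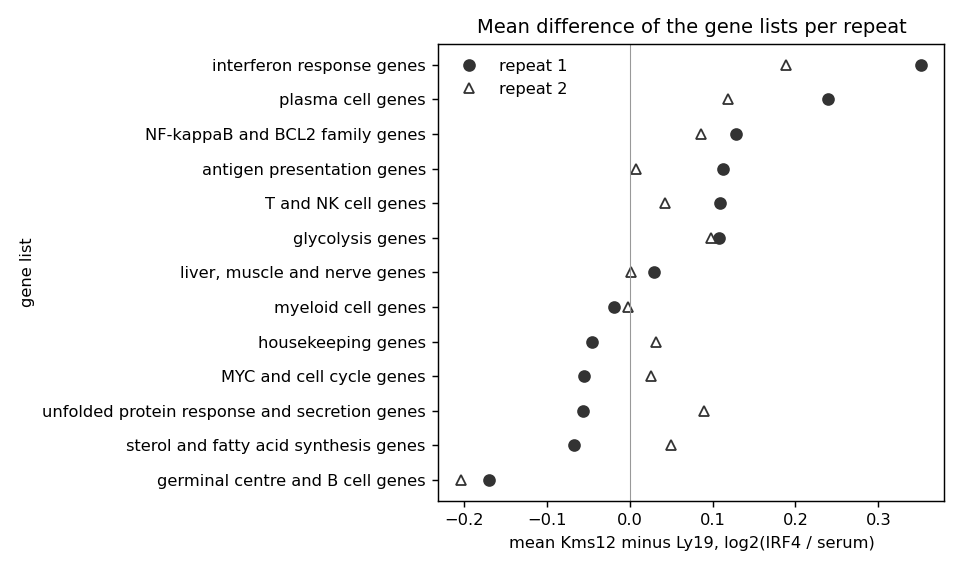
Mean Kms12 minus Ly19 difference of the log2 ratio of IRF4 to serum (horizontal axis) for each of the 13 gene lists (vertical axis), separately for repeat 1 (filled circles) and repeat 2 (open triangles). The interferon response and plasma cell lists lie above 0 in both repeats and the germinal centre and B cell list below 0, at -0.17 and -0.20.

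The other 10 lists were not called by camera. NF-kappaB and BCL2 family genes differed by 0.11 and glycolysis genes by 0.10 (adjusted p = 0.165 each), T and NK cell genes by 0.08 (adjusted p = 0.435) and antigen presentation genes by 0.06 (adjusted p = 0.63). Unfolded protein response and secretion genes differed by 0.02 (adjusted p = 0.63), liver, muscle and nerve genes by 0.02 (adjusted p = 0.435), and sterol and fatty acid synthesis genes by -0.01 (adjusted p = 0.434). Myeloid cell genes differed by -0.01 (adjusted p = 0.434), MYC and cell cycle genes by -0.01 (adjusted p = 0.371) and housekeeping genes by -0.01 (adjusted p = 0.36). Some large single differences in these lists came mostly from repeat 1, such as 2.14 in repeat 1 and 0.23 in repeat 2 at CDK6, 1.89 and 0.26 at ERN1, 1.57 and 0.26 at HK2, 1.06 and 0.40 at B2M, and 1.38 and 0.07 at RAB7. Others were large in both repeats, among them TNFAIP3 (1.60 and 1.08), CDKN1B (1.38 and 0.85), MYC (1.00 and 0.64) and MBP (-1.10 and -0.83). CFLAR, an inhibitor of death receptor signalling, differed by 0.91 (1.25 and 0.57; unadjusted p = 0.00663) without passing the threshold. Its window, too, was the one with the largest difference in the gene, so this unadjusted p was picked on the quantity it tests.

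Toward Ly19, the 111 genes with a called region included some of B cell identity and signalling, 6 of them in the germinal centre and B cell list. PAX5, the B cell lineage factor, was at 1.15 ± 0.11 in Ly19 and -0.03 ± 0.12 in Kms12, 992 bp inside the gene (chromosome 9, 37023050 to 37023856). BLK, a kinase of the B cell receptor pathway, was at 1.06 ± 0.13 and -0.27 ± 0.01 (chromosome 8, 11389857 to 11390258, 1299 bp inside). MS4A1, which encodes CD20, differed by -1.05, IRF8 by -1.05 and BANK1, a B cell adaptor, by -1.01. Other large differences were at CPEB4, an RNA-binding protein (-1.54), PRDM2 (-1.31) and PTPRC, which encodes CD45 (-1.46). The adjusted p after quantile normalisation was 0.0133 for PAX5, 0.00929 for BLK, 0.037 for MS4A1, 0.026 for IRF8, 0.0281 for BANK1, 0.00199 for CPEB4, 0.0065 for PRDM2 and 0.00369 for PTPRC, and 1 for each on the deposited ratios.

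CDKN2C, a cell cycle inhibitor, was at 1.43 ± 0.10 in Ly19 and -0.47 ± 0.21 in Kms12 (chromosome 1, 51148286 to 51149038, 1021 bp inside; adjusted p = 0.00199 after quantile normalisation). The serum signal there was lower in Kms12 than in Ly19, by -2.68 in repeat 1 and -2.58 in repeat 2, so that the Kms12 ratio at CDKN2C may not measure IRF4. At IRF8 the serum signal differed by -0.52 and -1.82, and at MBP by -0.90 and -1.01. In the called regions at CPEB4 it differed by -1.23 and -0.70, by -0.32 and -1.51, and by -0.67 and -0.54. At PTPRC it differed by -0.60 and -1.80 in the region of the window given above, and by -1.33 and -1.92 in a second called region (chromosome 1, 195338666 to 195339285). In a test chosen after the calls had been seen, 6 of 32 germinal centre and B cell genes had a region called toward Ly19 (BANK1, BRDG1, IRF8, MS4A1, PAX5 and SYK), 18.75% against 0.61% of other genes (Fisher exact test, adjusted p = 6.3e-07). The plasma cell gene IGJ (-1.11), CYBB of the myeloid list (-1.12 in its region, chromosome X, 37395205 to 37397754) and MBP of the nerve list (-0.97) also had such a region, each the only one of its list besides CDKN2C in the cell cycle list (adjusted p = 0.551 each).

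Within each line the comparison was IRF4 antibody against normal serum, with the dye fixed. RAB30, a Golgi GTPase, was at 1.52 ± 0.39 in Kms12 and 1.78 ± 1.11 in Ly19, and STK17B, a kinase linked to apoptosis, at 1.58 ± 0.74 and 1.29 ± 0.14. RNF168, a ubiquitin ligase of the DNA damage response, was at 1.27 ± 0.06 and 1.49 ± 0.42, and CASP8 at 1.30 ± 0.46 and 1.27 ± 0.09. These were among the 5 genes with the largest mean of both lines among windows enriched in both after quantile normalisation (highest adjusted p = 0.00389, at CASP8 in Ly19). The largest in Kms12 also included CDKN1B (1.64 ± 0.41), ARHGEF12, ENTH (1.38 ± 0.02), UBE2J1 (1.61 ± 0.64), SFRS2 (1.51 ± 0.46) and WEE1 (1.69 ± 0.98). Those in Ly19 included CAND1 (1.93 ± 1.65), FAM20B (1.59 ± 0.52), C6orf166 (1.68 ± 1.18), CDKN2C (1.51 ± 0.07), STIM2 (1.45 ± 0.01) and C13orf23 (1.40 ± 0.15).

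For the deposited ratios limma called 0 regions enriched or depleted in either line, with 48228 windows in Kms12 and 40057 in Ly19 at an unadjusted p below 0.05 for enrichment, and 8849 and 6616 for depletion (smallest adjusted p = 0.121). With the repeat number as a block it called 5217 enriched regions in Kms12 and 3993 in Ly19, and 236 and 71 depleted ones. After quantile normalisation the counts were 3766 and 5155 enriched, and 193 and 36 depleted. Of 16852 enriched windows in Kms12 and 24132 in Ly19, 8687 were shared, against 957 for independent lists. Both lists share any probe effects of dye and sequence, which could raise the overlap without binding.

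Within each line, unfolded protein response and secretion genes had a mean ratio of 0.36 ± 0.22 in Kms12 and 0.34 ± 0.32 in Ly19 (camera, adjusted p = 2.84e-08 and 6.54e-09). In Kms12 interferon response genes were at 0.32 ± 0.15 and plasma cell genes at 0.26 ± 0.13 (adjusted p = 2.84e-08 and 0.000934), and in Ly19 germinal centre and B cell genes were at 0.26 ± 0.05 (adjusted p = 5.04e-07). With an estimated correlation none of these was called (adjusted p = 0.557 and 0.537 for the first list, then 0.399, 0.399 and 0.459), nor was any other list. With the preset correlation camera also called housekeeping genes in both lines (0.24 ± 0.17 in Kms12 and 0.24 ± 0.22 in Ly19; adjusted p = 0.00905 and 0.000256), MYC and cell cycle genes (0.19 ± 0.10 and 0.20 ± 0.16; 0.0132 and 0.000951) and antigen presentation genes (0.20 ± 0.09 and 0.14 ± 0.01; 0.00335 and 0.0171). It further called NF-kappaB and BCL2 family genes (0.19 ± 0.05; adjusted p = 0.00428) and myeloid cell genes (-0.06 ± 0.09; 0.0286) in Kms12, and sterol and fatty acid synthesis genes in Ly19 (0.14 ± 0.12; 0.0256). Liver, muscle and nerve genes were at -0.09 ± 0.05 in Kms12 and -0.11 ± 0.07 in Ly19 (adjusted p = 0.000934 and 0.0171; adjusted p = 0.453 and 0.537 with an estimated correlation).

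After quantile normalisation 128 of 220 windows higher in Kms12 (58.18%) lay over 1000 bp downstream of the start, as did 43.75% of those higher in Ly19, against 33.26% of all tested windows. Windows enriched over serum also lay there more often than all tested ones, 50.22% of them in Kms12 and 41.86% in Ly19. Neighbouring windows overlap, so no p-value was computed.

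The element GAAANNGAAA, which interferon regulatory factors bind as a pair of half-sites, was searched in probe sequences, a test chosen after the files had been seen. Windows centred on the 3720 probes that carry it had a mean Kms12 minus Ly19 difference of 0.13 in repeat 1 and -0.02 in repeat 2, the highest of the 7 spacings in each repeat. The nearest other spacing lay 0.0109 lower in repeat 1 (SE of this margin 0.0107) and 0.0122 lower in repeat 2 (SE 0.0052). This SE counts windows as independent, although neighbours overlap and the element's windows correlate (0.0718, estimated by camera). It therefore cannot serve to judge the margins. Camera did not call the element against the other windows (adjusted p = 0.966; 0.983 with an estimated correlation). For GGAANNGAAA, bound by ETS factors with IRF4, spacing 2 was not the highest in either repeat. Of the 66 regions higher in Kms12, 5 carried GAAANNGAAA (7.58%, against 2.88% of random runs; Fisher exact test, p = 0.0497, adjusted p = 0.199), and 5 carried the same half-sites at spacing 3 (adjusted p = 0.125). Of the 131 regions higher in Ly19, 6 carried GAAANNGAAA (4.58% against 2.52%, adjusted p = 0.262).

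**Figure D4:**
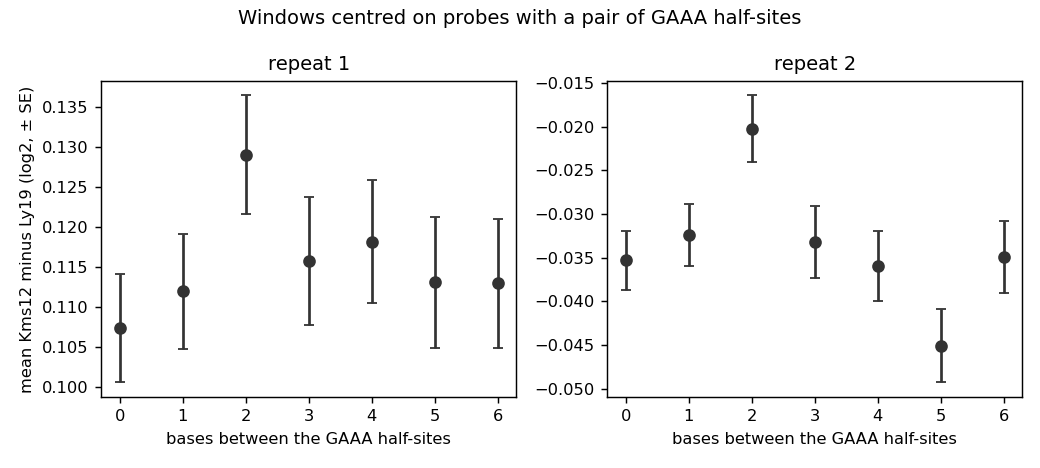
Mean Kms12 minus Ly19 difference of the log2 ratio of IRF4 to serum (vertical axis, with SE over windows) for windows centred on probes with a pair of GAAA half-sites, against the number of bases between them (horizontal axis), in repeat 1 and repeat 2. In both panels the highest point is at 2 bases, at 0.13 and -0.02, and the next highest point lies 0.0109 and 0.0122 lower. The SE counts overlapping windows as independent.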

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

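The other splits of the arrays, the GC test on the Ly19 side and the rule that a motif margin must exceed 2 SE are tests chosen only after the result was seen, and so was the use of quantile-normalised calls; for the other tests the prediction was written down before the result was seen, although the motif search in probes and the removal of a GC trend had themselves been added after the files were seen. The remark on single arrays replaces an earlier test, the share of regions with Kms12 above Ly19 in both repeats, which came out at 66 of 66 but was fixed by how the regions are selected.

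Among 85 named genes, 37 had IRF4 over serum above 0 in every array of one line and below 0 in every array of the other, 20 of them with Kms12 above 0 and 17 with Ly19. Windows named for the comparison of the lines were picked for a large difference, so this count is partly fixed by that choice. No share over all windows was computed beside it. For these genes the difference between the lines was not tested beyond the comparisons in the report, where none passed on the deposited ratios. Toward Kms12 the mean differences (log2, Kms12 minus Ly19) were 1.93 at C21orf25, 1.67 at DENND2C, 1.64 at CASP4, 1.58 at GIMAP2, 1.53 at ARHGAP24, 1.51 at SSTR2, 1.45 at SMOC1 and 1.41 at TP73L. They were 1.35 at PRDM1 (in the window 2129 bp inside the gene), 1.33 at IL15, 1.19 at CDK6, 1.15 at LRIG3, 1.12 at ELL2, 0.94 at TRAF2, 0.92 at IRF4, 0.91 at CANX and 0.90 at IFIT3. In that PRDM1 window Ly19 repeat 2 lay below 0 because of 1 probe at -1.246, while its other probes lay between -0.03 and 0.30. TNFSF10 differed by 0.89, MYC by 0.82 and PSMB9 by 0.58.

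Toward Ly19 the mean differences were -1.96 at CDKN2C, -1.54 at CPEB4, -1.46 at PTPRC, -1.34 at BLK, -1.21 at CD86, -1.21 at CYBB, -1.05 at MS4A1, -1.05 at IRF8 and -1.01 at BANK1. They were -0.97 at MBP, -0.81 at UBASH3A, -0.70 at ELOVL6, -0.68 at MYL1, -0.67 at CLEC7A, -0.62 at KLRD1, -0.60 at TLR4 and -0.47 at SLC2A3. The gene lists called by camera between the lines were plasma cell genes (0.18), germinal centre and B cell genes (-0.19) and interferon response genes (0.27), with the preset correlation only.

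The 66 regions higher in Kms12 after quantile normalisation kept 0.985 of their median difference with the GC trend removed from the deposited ratios. The median was 1.16 before (quartiles 1.08 to 1.33) and 1.14 after (1.06 to 1.30). Mean ratios in bins of GC content lay between -0.33 and 0.42 in every array, so removal could change these differences only little. This argues against a GC trend as the source of their size, but not of the call. The call itself ended when the trend was removed before quantile normalisation: the median difference went from 1.105 to 1.155 and the median residual SD from 0.20 to 0.19, but the prior degrees of freedom of the spread fell from 21.05 and 16.43 to 9 and 5.95, so that the median adjusted p rose from 0.0343 to 0.159. A single aberrant array would enter the other 2 splits of the arrays as well, and these called 0 regions (share 0 of the 197 of the real split). However, 3 splits are too few for a test of chance. The comparison holds only after quantile normalisation, which gives all arrays 1 distribution. On the deposited ratios all 3 splits called 0 regions, and counts there depended strongly on which repeat was left out. An aberrant array is therefore not excluded. IRF4 binding at its DNA element cannot be told apart from no such binding. The prediction written beforehand asked only that spacing 2 exceed every other half-site spacing in both repeats, and it did, by 0.0109 and 0.0122. Under the 2 SE rule added later this was undecided (within 2 SE in repeat 1, 2.33 SE in repeat 2). That SE counts overlapping windows as independent, so the margins have no valid error to be judged by. A biological difference between a myeloma and a lymphoma line stays open, as a hypothesis that may account for PRDM1 and ELL2.

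The next pattern is the set of 131 regions higher in Ly19 after quantile normalisation. Here too a GC trend is argued against only as the source of the size of the differences (0.983 of the median kept). The call again ended with the trend removed before quantile normalisation: the median difference went from -1.136 to -1.051, the median residual SD from 0.219 to 0.238 and the median adjusted p from 0.0317 to 0.191. At CDKN2C and FAF1 the serum signal was lower in Kms12, the weakest difference over the regions and repeats being -2.33 (log2), consistent with DNA missing from Kms12 there; the ratios at this locus may then say nothing about IRF4 in Kms12. At the other 129 regions the share with serum lower by over 1 in both repeats was 0.0155 (2 regions, at PTPRC and MCP). Their median serum difference was 0.075 in repeat 1 and -0.367 in repeat 2. This argues against a loss of DNA as large as at CDKN2C for most of the set. A smaller loss, such as of 1 copy, need not pass this bound and stays open. The Ly19 side had been planned also as a check on the rate of false calls, and it called more regions than the Kms12 side (131 against 66). The calls alone therefore do not show IRF4 binding in either line. The difference between the lines at B cell genes such as PAX5 and MS4A1 stays open as a biological one, untested.

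The last pattern is the enrichment over serum shared by both lines after quantile normalisation, 8687 windows against 957 for independent lists. With the GC trend removed first, 4755 windows were shared, a share of 0.547, which lies between the bounds set beforehand. The lists themselves had shrunk to 11967 windows in Kms12 and 15184 in Ly19, and 427.6 shared windows would be the number for independent lists. The remaining excess argues against a GC trend as the whole source. How much of the overlap a GC trend made cannot be told apart from other sources. A dye effect of the probes with no IRF4 binding in Ly19 also stays open. In Ly19 the half-site spacing of 2 lay 0.0017 and 0.002 under the highest other spacing (margins -0.0017 and -0.002, SE 0.0097 and 0.0051). The prediction written beforehand for such a dye effect was thereby met, but the 2 SE rule added later left it undecided. This SE, too, counts overlapping windows as independent. Without dye-swapped arrays no test here separates the antibody from Cy5.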

How the results depend on the processing

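Alternatives with a common background, with GC trend removal, and with scaling or quantile normalisation joined to the block were tests chosen after seeing the data. Limits of the data include 2 repeats per line, no dye swap, the smaller spread of the ratios in repeat 2, and a median Cy3 probe at 1.69 to 2.22 times the negative controls. For the moved counts in this part the cause was not tested, except that leaving out a repeat leaves 1 array of a line, which is then assumed to vary like the other line.

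Every region count was 0 on the deposited ratios, and 0 as well with other window sizes, single probes, other thresholds, no centring, loess, other probe filters, joining within 500 bp and the GC trend removed alone. Between the lines there were also 0 regions when scaled without the block (smallest adjusted p 0.0893), with a common background (0.373), with that and the block (0.095), and with the GC trend removed before quantile normalisation (0.127). Regions higher in Kms12 and in Ly19 numbered 66 and 131 with quantile normalisation, 67 and 113 with a trended and robust spread, 185 and 359 when scaled with the block, 480 and 1040 when quantile-normalised with the block, and 9 and 7 with the GC trend removed and the block. All 231 and 411 windows of the quantile-normalised calls were also called with scaling and the block and with quantile normalisation and the block. The replicate block alone left both counts at 0 (smallest adjusted p 0.259; 16741 and 13071 windows at an unadjusted p below 0.05). Genes with a region higher in Kms12 numbered 59, 64, 164, 415 and 8 in the same order.

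Counts of enriched regions in Kms12 and Ly19, depleted regions in Kms12 and Ly19, and windows enriched in both were, in this order, 2797, 4150, 38, 56 and 5552 when scaled. They were 3766, 5155, 193, 36 and 8687 when quantile-normalised, 5217, 3993, 236, 71 and 8756 with the replicate block, and 2825, 3167, 65, 43 and 4083 with the spread of 1 line only. With a common background they were 3295, 3033, 206, 83 and 5002, and with the block added 5909, 5770, 586, 522 and 14372. Scaling with the block gave 3190, 4293, 55, 68 and 6521, and quantile normalisation with the block 3814, 5172, 194, 39 and 8841. GC trend removal gave 3860, 3140, 412, 103 and 5778 with the block, and 2803, 3527, 165, 124 and 4755 before quantile normalisation.

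With 1 repeat of a line left out, regions higher in Kms12 ranged from 0 to 2327, regions higher in Ly19 from 0 to 203 and genes from 0 to 2060. Enriched regions ranged from 1 to 12143 in Kms12 and 0 to 3167 in Ly19, depleted regions from 0 to 2301 and 0 to 67, and shared windows from 0 to 9158. The largest counts toward Kms12 came without Kms12 repeat 2. Lists with an excess of called genes ranged from 0 to 4 and lists called by camera from 3 to 6.

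Here and in the range above, lists with an excess of called genes were counted toward Kms12 only. They numbered 1 with quantile normalisation, 1 when scaled with the block and 3 when quantile-normalised with the block, against 0 under the other settings that keep every array. Toward Ly19 the germinal centre and B cell list had an excess with quantile normalisation (Fisher exact test, adjusted p = 6.3e-07). Camera called 3 lists, 4 with all probes of a gene (NF-kappaB and BCL2 family genes added, adjusted p 0.0339), 4 without Kms12 repeat 1 and 6 without Ly19 repeat 1 or repeat 2, but 0 with an estimated correlation. Unfolded protein response and secretion genes were among the added lists without Kms12 repeat 1 and without either Ly19 repeat, and the plasma cell list was lost without Kms12 repeat 1 (adjusted p 0.0684, against 5.29e-05 to 0.0413 under the other settings with the preset correlation). The replicate block changed none of the 3 list calls.

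For the differences at 74 named windows, 1620 values under other settings included 1470 on the same side of the threshold, 148 that now passed it and 2 of opposite sign; with a repeat left out, 296 included 241, 51 and 4. The difference at LDHB reversed with 250 bp windows (-0.0082), with single probes (-0.0259) and without Kms12 repeat 1 (-0.0764, against 1.01 without Kms12 repeat 2). It reversed at SSR3 without Ly19 repeat 1 (0.051, against -1.57 without Ly19 repeat 2), and without Kms12 repeat 1 at DHCR7 (-0.0407, against 1.28 without Kms12 repeat 2) and RAB7 (-0.143, against 1.58). IRF4 over serum in Kms12 at the enriched CDKN2C window reversed with 250 bp windows (0.0331) and single probes (0.0043).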

Other observations

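The tests on single genes in this part were chosen after their values were seen.

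Beyond the genes named by rule, and with IFIH1, which the rule names by another window, several genes of innate immune sensing and of inflammatory signalling had a region called higher in Kms12 after quantile normalisation. CASP1, an inflammatory caspase, lay at 1.20 ± 0.38 in Kms12 and -0.01 ± 0.03 in Ly19 (SD, n = 2; limma, adjusted p = 0.0307), 1024 bp inside the gene. IFRG28 (now RTP4), induced by interferon, lay at 1.03 ± 0.42 and -0.13 ± 0.19 at its start (adjusted p = 0.026). SAMD9L lay at 1.11 ± 0.29 and 0.03 ± 0.19 (adjusted p = 0.0401), IFIH1 at 1.13 ± 0.55 and 0.07 ± 0.08 (adjusted p = 0.043), and the cytokine gene IL15 at 1.11 ± 0.65 and -0.23 ± 0.08 (adjusted p = 0.0122). On the deposited ratios the adjusted p of each was 1, and with the GC trend removed before quantile normalisation no region was called (smallest adjusted p 0.127). These genes form no list fixed beforehand and their number was not tested. AIM2, IFI16, PYHIN1 and TLR10, also of innate immune sensing, had a region called higher in Ly19, and the interferon list had 1 of 41 members with a region called toward Kms12. The interferon list as a whole differed by 0.17 to 0.37 over the settings tried.

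Toward Ly19, CD86, a costimulatory molecule of activated B cells, lay at 0.86 ± 0.03 in Ly19 and -0.35 ± 0.18 in Kms12, 2295 bp inside the gene (adjusted p = 0.0122 after quantile normalisation and 1 on the deposited ratios). The germinal centre and B cell list differed by -0.28 to -0.13 over the settings tried, and the plasma cell list by 0.09 to 0.27.

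The arrays differed in how the log ratio depended on probe GC content. In Kms12 repeat 1 the mean ratio went from 0.42 at under 30% GC to -0.29 at over 70% on the first array design, whereas in Kms12 repeat 2 it went from -0.09 to -0.13 with a maximum of 0.08 between. In Ly19 it went from 0.25 to -0.03 in repeat 1, with a minimum of -0.22 between, and from 0.08 to -0.33 in repeat 2. On the deposited ratios, the split of the arrays into repeat 1 and repeat 2 had 52311 windows at an unadjusted p below 0.05, against 12759 for Kms12 and Ly19, and 0 called regions for both.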
